A study of Rattus norvegicus with 14 samples.

How the data were processed

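Hippocampal tissue of Wistar rats (180 to 220 g per the labels) was measured by RNA sequencing in 14 samples. Total RNA was extracted with TRIzol, mRNA was captured on beads, and libraries were sequenced on a BGI T7 instrument per the labels. The labels give 3 groups: control animals that received vehicle (n = 4), animals of the seizure model made with PTZ that received vehicle (n = 5), and animals of the same model that received Q808 (n = 5, written PTZ+Q808 here). PTZ is pentylenetetrazole, a convulsant that blocks GABA-A receptors. Q808 is a compound known here by its code name alone. Dose, time of sampling, sex and the order of treatments were not given in the sources used here, and nothing beyond the design text says which animal each replicate came from.

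The deposited values are FPKM, fragment counts scaled by transcript length and by library total, as computed by the authors for each gene and sample. The authors name Trimmomatic, HISAT2, Cufflinks, HTSeq, DESeq, Bowtie2, StringTie and SAMtools without the role or version of each, and the genome build was not stated, so no chromosomal position is given. Each file lists 22601 genes with a symbol and database identifiers. Symbols are those of the files, and 20633 gene identifiers were matched to a current RefSeq gene table that was used for names only. A spreadsheet had turned 12 symbols into dates, and these were read through their gene identifiers. Library totals and raw counts were not used here, since the values are already scaled, so the depth behind each value is unknown and no counting interval is given. Relative depth was estimated from the smallest steps between low values of 1565 genes, of which 90.0% had all positive values at whole multiples of 1 step (tolerance 0.12 of a step). It ran from 0.886 to 1.07 over the 14 libraries. Only ratios in a window around equal depth were searched, so a large difference in depth could not have been returned.

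Genes with an FPKM of at least 1 in at least 4 samples were tested (12744 genes). Values were transformed as log2(FPKM + 1), with no further scaling. The 3 groups were fitted together in limma 3.58.1 (R 4.3.3, data.table version 1.17.8) with a mean-dependent prior variance, which left 11 residual degrees of freedom. The 3 comparisons were PTZ versus control, PTZ+Q808 versus PTZ and PTZ+Q808 versus control. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 12744 genes of a comparison. Log2 changes are differences of group means on this scale, so the pseudocount of 1 shrinks them for genes of low FPKM. Errors of log2 changes are standard errors, and FPKM values are group means with SD. Figures were drawn with matplotlib 3.10.9.

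The groups, tests, thresholds, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Named genes were, per comparison, the 10 highest and the 10 lowest log2 changes among called genes whose groups did not overlap in any library, whose higher group had a mean FPKM of at least 1 and whose symbol was not a placeholder. To these were added up to 4 members with the smallest p from each gene list that was called or that held a called gene. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were named and said not to pass. A gene named in 1 comparison could be given in the others, and any other gene named was chosen after its values were seen. Some genes that met this rule are not reported.

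Of 800 list members, 784 were found in the files, and 36 lists were tested. A gene could belong to more than 1 list, so the list tests were not independent of each other. A list of mitochondrially encoded genes had fewer than 2 tested members and was not tested. Lists were tested with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 108 tests. The same lists were tested with camera at an estimated correlation, with fry, and with an exact permutation test of the list mean per library. The last of these was added after the data had been seen, and the smallest p it can give is 0.00794. Of the 19 list calls at the preset correlation, 0 held with an estimated correlation (smallest adjusted p = 0.998), 0 held with fry, and 5 had an exact permutation p under 0.05 before adjustment. For each list the members past the threshold were also counted with p adjusted over the list alone.

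Alternatives were a pseudocount of 0.1, no filter except genes at 0 in every sample, a minimum FPKM of 5, median-of-ratios scaling, rescaling to an equal total per library, quantile normalization, a fit of only the 2 groups compared, weights per library, a robust prior, the replicate number as a block, 2 other thresholds, and leaving out each library in turn. Further terms and subsets were added after the data had been seen, namely a term for Y-linked transcripts (at 1 FPKM or more), log2 Ttr as a covariate, the exact test of list means, and a fit without the 3 libraries with Ttr under 400 FPKM. A count-based test was not run, because the files used hold FPKM alone. Correlations of effects that share libraries were compared with 100 simulated sets without any group difference and with splits of the shared group.

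The procedure was tested on simulated data of the same group sizes. A change of 0.5 on the log2 scale was recovered for 71%, 74% and 76% of 100 shifted genes in the 3 comparisons, in the order given above. False calls were 6 of 172, 6 of 174 and 8 of 177. A shifted list was called in each comparison, with 0 other lists called. Genes were simulated as independent, so false list calls from correlation between genes could not arise there. The shifted genes were drawn from those above a minimum mean level, so recovery at low FPKM was not tested.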

Results

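Hippocampal transcript levels were measured in 4 control rats, 5 rats of the PTZ seizure model and 5 rats of that model that received Q808. The sum of FPKM ran from 383126 to 419358 per library, and Spearman correlations across genes between pairs of libraries ran from 0.980 to 0.988. The Y-linked genes Kdm5d, Eif2s3y and Ddx3 were each at 1 FPKM or more (5.75 to 33.4) in 2 of 4 control, 3 of 5 PTZ and 3 of 5 PTZ+Q808 libraries, named below as those with Y-linked transcripts. They were at most 0.549 FPKM in the other 6, and sex was not given in the labels. Ttr, a choroid plexus transcript, was 54.5 FPKM in control replicate 3, 113 in PTZ replicate 2 and 329 in PTZ+Q808 replicate 1, against 1315 to 7125 in the other 11 libraries. The mean log2 value of choroid plexus markers was 3.51 ± 1.51 (SD, n = 4) in control, 3.59 ± 1.14 (n = 5) in PTZ and 3.65 ± 1.25 (n = 5) in PTZ+Q808. Control replicate 2 held the striatal transcripts Drd2 (29.4 FPKM) and Ppp1r1b (241 FPKM) above all other controls. PTZ+Q808 replicate 3 held the pituitary hormone transcripts Prl (395 FPKM) and Gh1 (206 FPKM).

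The comparison of PTZ with control asked which hippocampal transcripts differed in the seizure model. Transcripts of 4 genes rose and 0 fell. Cyr61, which encodes a secreted matricellular protein (gene identifier 83476), rose from 1.54 ± 0.439 FPKM (SD, n = 4) in control to 15.5 ± 8.60 (n = 5) in PTZ, a log2 change of 2.56 ± 0.358 (SE, adjusted p = 0.0263). Apold1, an activity-responsive gene of vascular endothelium (444983), rose from 5.16 ± 1.54 to 34.7 ± 11.9 FPKM, with a log2 change of 2.50 ± 0.279 (adjusted p = 0.0041). Zfp36 (79426), whose product promotes decay of AU-rich mRNAs, rose by 1.12 ± 0.174 on the log2 scale (3.92 ± 1.00 to 9.78 ± 2.36 FPKM, adjusted p = 0.0455). Nfkbia (25493), which encodes the NF-kB inhibitor IkB-alpha, rose by 0.92 ± 0.133 (15.6 ± 2.64 to 30.3 ± 4.79 FPKM, adjusted p = 0.0263). For each of the 4 genes all 5 PTZ libraries lay above all 4 control libraries, as shown in the plot of the 4 genes per library. The next genes by p did not pass. Those with lower values were the glial transcription factor Sox9 (log2 change -0.81, adjusted p = 0.0836), the mitochondrial citrate carrier Slc25a1 (-0.32, 0.154), Hhex (-0.50, 0.239), Brat1 (-0.26, 0.239) and Bola1 (-0.35, 0.239).

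**Figure D1:**
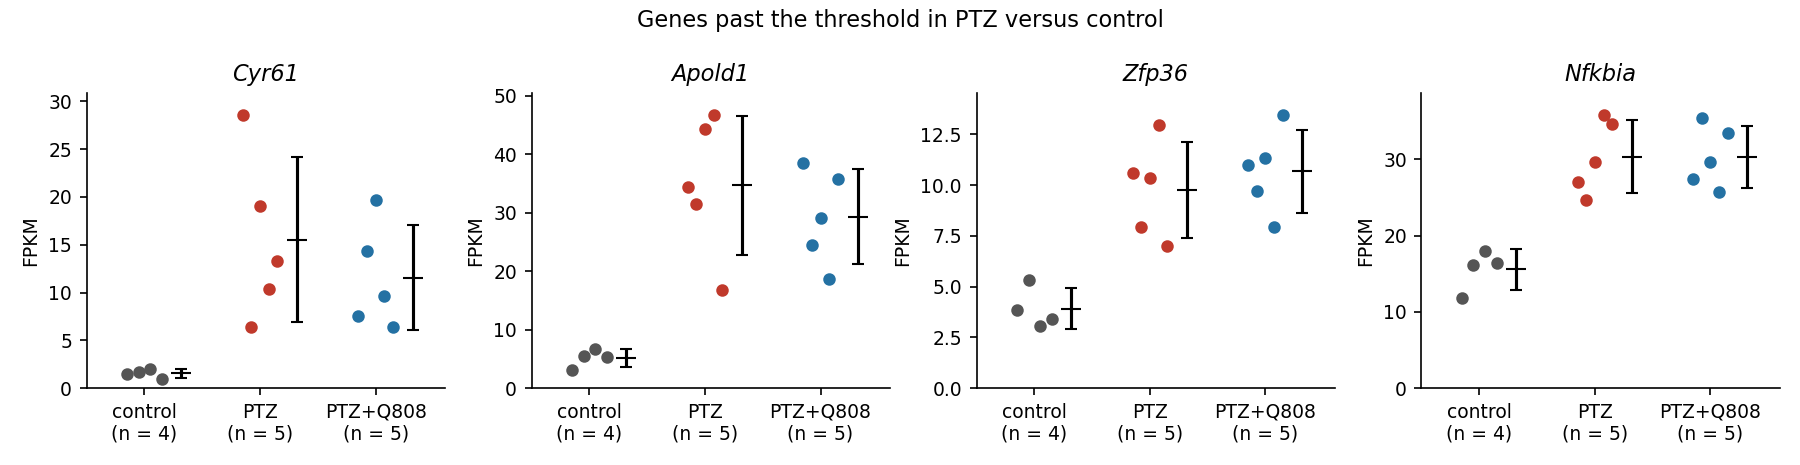
FPKM of Cyr61, Apold1, Zfp36 and Nfkbia in each library of control (n = 4), PTZ (n = 5) and PTZ+Q808 (n = 5), with 1 point per library and, beside the points, the mean with SD as error bars. Means were 5.16, 34.7 and 29.4 FPKM for Apold1 and 15.6, 30.3 and 30.3 FPKM for Nfkbia.

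Immediate early genes, which are transcribed within minutes of neuronal activity, were higher as a group in PTZ. All 34 measured members had higher means than in control, with a median log2 change of 1.01 (adjusted p = 1.39e-27 by camera at the preset correlation, adjusted p = 0.998 with an estimated correlation). Members past the threshold numbered 2 over all genes tested (Apold1 and Cyr61) and 20 adjusted over the list alone. The MAP kinase phosphatase gene Dusp1 (log2 change 1.46, 26.1 to 72.6 FPKM, adjusted p = 0.215) and the transcription factor gene Maff (1.28, adjusted p = 0.239) passed over the list alone. The list mean was 3.40 ± 0.257 (SD, n = 4) in control and 4.60 ± 0.652 (n = 5) in PTZ (exact permutation p = 0.0159, adjusted over 108 tests at least 0.855). Glucocorticoid-induced genes were also higher as a group (13 of 20 members with positive values, median log2 change 0.32, adjusted p = 0.000173, adjusted p = 0.998 with an estimated correlation, exact permutation p = 0.0794). Of these Nfkbia passed over all genes. Nfkbia, Errfi1 (0.76) and Sgk1 (0.98) were the 3 past the threshold adjusted over the list alone. Cdkn1a had a value of 0.68. Cholesterol synthesis genes were lower as a group (3 of 19 members with positive values, median -0.10, adjusted p = 0.00131, adjusted p = 0.998 with an estimated correlation, exact permutation p = 0.0952). Members past the threshold were 0 over all genes and 2 adjusted over the list alone. These were Fdft1, encoding squalene synthase (-0.22, 44.6 to 38.2 FPKM), and Dhcr7, encoding 7-dehydrocholesterol reductase (-0.25). Mvd and Mvk both had values of -0.21. With the preset correlation kept, these 3 lists were called in all 27 other settings run on each. Maff reached 6.53 FPKM in PTZ replicate 4, apart from the other PTZ libraries.

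Another 9 lists were called in PTZ versus control by camera at the preset correlation, each with an adjusted p of 0.998 with an estimated correlation. Their exact permutation p was 0.0238 for NF-kB, 0.0556 for CA1, 0.127 for neocortex, 0.135 for circadian, 0.23 for synaptic, 0.365 for channel, 0.365 for myelinating, 0.476 for meningeal and 0.492 for striatum lists (adjusted over 108 tests at least 0.855). Some called lists shared members. The immediate early list shared Per1 with the circadian and glucocorticoid lists, Nr4a2 with the neocortex list and Homer1 with the synaptic list. Nfkbia was in the NF-kB and glucocorticoid lists, and Dcn in the CA1 and meningeal lists. These calls are thus not separate findings, and the lists were not tested without shared members. Genes of NF-kB and innate immune signalling were higher (median log2 change 0.02, mean 0.17, adjusted p = 0.0254). Nfkbia passed over all genes, and Nfkbia, Ifit3 (1.26), Nfkbiz (0.42) and Cebpb (0.48) were the 4 past the threshold adjusted over the list alone. Circadian clock genes were higher in 13 of 17 members (median 0.11, adjusted p = 0.0254), with 0 past the threshold over all genes and Bhlhe40 (0.58) adjusted over the list alone. Nfil3 (0.53), Per1 (0.69) and Nr1d2 (0.12) did not pass. Synaptic vesicle and scaffold genes (22 of 29 members with positive values, median 0.06, adjusted p = 0.0221) and voltage-gated channel genes (26 of 42, median 0.07, adjusted p = 0.0375) were higher. Both had 0 members past the threshold over all genes and 0 adjusted over the list alone. The synaptic members of smallest p were Nlgn1 (0.23), Homer1 (0.32) and Sv2b (0.22), among others. The channel members of smallest p were Kcnh7 (0.50), Cacna2d1 (0.27), Cacna1e (0.22) and Cacnb4 (0.28). Markers of CA1 pyramidal cells (8 of 9 members with positive values, median 0.23, adjusted p = 0.0233) and of neocortex (10 of 13, median 0.22, adjusted p = 0.0221) were higher with 0 members past the threshold over all genes. Over the list alone 0 CA1 markers passed (Mpped1 had a value of 0.17, Nov 0.23 and Dcn 0.35), and 1 neocortex marker, Etv1 (0.29). Nr4a2 (1.03), Mef2c (0.43) and Tbr1 (0.41) did not pass. Meningeal and fibroblast markers were higher in 15 of 15 members (median 0.36, adjusted p = 0.0375), among them the collagen genes Col1a2 (0.73) and Col3a1 (0.61), Mgp (0.41) and Dcn. Their list mean was above the controls (2.31 to 2.85) in PTZ replicates 1 (4.19) and 2 (3.31) and 2.30 to 2.58 in PTZ replicates 3, 4 and 5. Myelinating oligodendrocyte markers were lower (1 of 16 members with positive values, median -0.23, adjusted p = 0.0375), among them Mag (-0.27), Cnp (-0.27) and Fa2h (-0.33). The meningeal and myelinating lists had 0 members past either threshold. Striatum markers were lower (0 of 12 members with positive values, median -0.63, adjusted p = 0.0124, 0 members past either threshold), among them Drd2 (-0.93), Gpr6 (-0.81), Ppp1r1b (-0.69) and Syndig1l (-0.89). Among PTZ libraries, replicate 4 stood apart for Nr4a2 (59.1 FPKM), Per1 (26.7), Nfil3 (9.96), Ifit3 (6.16) and Homer1 (25.4), and replicate 1 for Col1a2 (9.35). The striatum call rested on control replicate 2, whose list mean was 5.42 against 2.40 to 2.81 in the other controls. Without control replicate 2 the direction turned (median 0.07, adjusted p = 0.433, range over alternatives 4.39e-06 to 0.433). Leaving out control replicate 2 also ended the calls of CA1, circadian, meningeal, myelinating, neocortex, synaptic and channel lists (highest adjusted p over all alternatives of these lists 0.112 to 0.804). List calls were ended in addition by leaving out control replicate 1 (CA1, circadian, meningeal, myelinating, neocortex, channels) or control replicate 3 (meningeal, NF-kB, channels). Calls also ended without PTZ replicate 1 (meningeal, myelinating, NF-kB), PTZ replicate 2 (CA1, meningeal, channels), PTZ replicate 3 (circadian, myelinating, neocortex, NF-kB, synaptic, channels), PTZ replicate 4 (CA1, circadian, myelinating, neocortex, NF-kB) and PTZ+Q808 replicate 3 (channels), with a highest adjusted p of 0.131 for the NF-kB list. Other settings ended calls too. The meningeal call ended with a pseudocount of 0.1, a minimum FPKM of 5, median-of-ratios scaling, rescaling to an equal total, weights per library, a Y-linked term or without the 3 libraries low in Ttr, and was kept in 15 of 27 alternatives. Quantile normalization ended the myelinating call, no filter the NF-kB call and a minimum FPKM of 5 the NF-kB and striatum calls. Weights per library ended the myelinating, striatum and synaptic calls, and rescaling to an equal total, a Y-linked term or leaving out the libraries low in Ttr the channel call.

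Unadjusted p was under 0.05 for 1034 genes in PTZ versus control (637 by chance), and the 2 groups did not overlap for 386 genes, 3.03% against 1.59% by chance. The count of 4 genes fell to 1 without control replicate 1, 3 or 4 or PTZ replicate 3 or 4, to 2 without PTZ replicate 5 or PTZ+Q808 replicate 3, and to 0 when only the 2 groups compared were fitted or with a replicate block. Among libraries with Y-linked transcripts (3 PTZ, 2 control) 1 gene passed, LOC108348142. Among those without (2 PTZ, 2 control) 3 passed, Apold1, Fos and Npas4. The PTZ effect on the mean of immediate early genes was 0.97 with and 1.63 without Y-linked transcripts (difference 0.66, exact permutation p = 0.533). Exchanging treatments within these subsets gave an effect of 1.30 (exact permutation p = 0.0167, the smallest possible).

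The comparison of PTZ+Q808 with PTZ asked what Q808 changed in the seizure model. No transcript passed in limma (0 genes, smallest adjusted p = 0.622, 783 genes with an unadjusted p under 0.05 against 637 by chance). For the 4 genes that rose in PTZ the difference between PTZ+Q808 and PTZ was smaller than the spread between replicates. Nfkbia was 30.3 ± 4.79 FPKM (SD, n = 5) in PTZ and 30.3 ± 4.05 (n = 5) in PTZ+Q808, and Zfp36 was 9.78 ± 2.36 and 10.7 ± 2.04. Apold1 was 34.7 ± 11.9 and 29.4 ± 8.12 FPKM, and Cyr61 was 15.5 ± 8.60 and 11.5 ± 5.49. In this order their log2 changes were 0.00 ± 0.125 (SE), 0.13 ± 0.164, -0.20 ± 0.263 and -0.35 ± 0.338 (adjusted p = 0.997, 0.935, 0.936 and 0.924).

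The genes of smallest p did not pass in PTZ+Q808 versus PTZ. Higher values were seen for Zrsr2, encoding a splicing factor of minor introns (log2 change 0.29, 8.09 to 10.1 FPKM, adjusted p = 0.622), and for Prtn3, encoding the neutrophil granule protease proteinase 3 (0.78, 0.713 to 1.93 FPKM, adjusted p = 0.76). At the same adjusted p of 0.76, values were higher for Krt26, encoding a keratin (0.42), Mtif2, encoding a mitochondrial translation initiation factor (0.32), and Ggnbp2 (0.30, 15.7 to 19.6 FPKM). Lower values, also at an adjusted p of 0.76, were seen for Tnfrsf25, encoding death receptor 3 (-0.41), Wbscr27 (-0.57), Stau1, encoding a double-stranded RNA binding protein of mRNA transport (-0.17), Osbp2, encoding an oxysterol binding protein (-0.21), and Ythdf1, encoding an N6-methyladenosine reader (-0.16). Oxidative stress response genes, the targets of Nrf2, were the 1 list called. They were higher in 14 of 19 members (median log2 change 0.07, adjusted p = 0.0451, adjusted p = 0.998 with an estimated correlation, exact permutation p = 0.183), with 0 members past the threshold over all genes and 0 adjusted over the list alone. Their members of smallest p were the superoxide dismutase genes Sod1 (0.20, 235 to 272 FPKM, adjusted p = 0.77) and Sod2 (0.07), malic enzyme gene Me1 (0.13) and ferritin light chain gene Ftl1 (0.07). The call ended without control replicate 1 or 2, PTZ replicate 2, 3 or 4 or PTZ+Q808 replicate 2 or 3. It also ended with FPKM rescaled to an equal total, quantile normalization, weights per library or a replicate block, and without the 3 libraries low in Ttr (adjusted p 0.0224 to 0.31 over all alternatives).

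Immediate early genes did not pass as a list in PTZ+Q808 versus PTZ (adjusted p = 0.173), with list means of 4.78 ± 0.813 (SD, n = 5) and 4.60 ± 0.652 (n = 5). The effect on this list was 0.19 with and 0.17 without Y-linked transcripts (exact permutation p of the difference = 0.983). Within those subsets 1 gene passed in each, LOC108348142 with (3 against 3 libraries) and Nhp2 without (2 against 2), both named after their values were seen. Of the 4 genes called in PTZ versus control, 0 were called in the opposite direction under Q808, which was fixed in advance by the 0 genes called there. Across the 12744 genes, which are not independent replicates, the PTZ effect and the Q808 effect had r = -0.0189, where the shared PTZ libraries alone gave -0.469 in simulated data. With the PTZ libraries split so that none was shared, the median r was 0.325 (0.106 to 0.424 over 20 splits). The sign of r turned without PTZ+Q808 replicate 2 (0.065) or 4 (0.0782). Groups did not overlap for 99 genes, 0.777% against 0.794% by chance.

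The comparison of PTZ+Q808 with control asked which transcripts differed from vehicle-treated rats after both PTZ and Q808. It gave 366 called genes, 247 higher and 119 lower, with a median absolute log2 change of 0.38 and 35 genes past 1.5-fold. Atf3, a stress-induced transcription factor gene, rose from 0.673 ± 0.122 FPKM (SD, n = 4) to 19.9 ± 16.6 (n = 5), a log2 change of 3.02 ± 0.745 (SE, adjusted p = 0.046). In PTZ it was 8.81 ± 11.1 FPKM, where replicate 4 alone reached 28.7. Npas4, an activity-dependent neuronal transcription factor gene, rose from 4.16 ± 0.852 to 37.9 ± 25.1 FPKM (2.54 ± 0.591, adjusted p = 0.0377). Fos, an AP-1 subunit gene, rose from 16.2 ± 5.36 to 92.1 ± 54.9 FPKM (2.19 ± 0.53, adjusted p = 0.0422). Apold1 (2.29, adjusted p = 0.00823), Cyr61 (2.21, 0.0128) and Gadd45g (1.80, 0.0482) rose. Dusp1 (1.49, 0.0226), Maff (1.44, 0.0226), Zfp36 (1.25, 0.00823) and Nfkbia (0.93, 0.00893) also rose. Of the 10 named genes that fell, C1qtnf9 changed by -0.90 (adjusted p = 0.0331), Sox9 by -0.73 (0.0226, 7.24 to 4.00 FPKM), the ephrin receptor gene Epha8 by -0.70 (0.0322) and the proto-oncogene Mycn by -0.63 (0.0215). The others were the Wnt pathway inhibitor gene Axin2 (-0.60, 0.0381), Rsrp1 (-0.58, 0.0331), the homeobox gene Hhex (-0.57, 0.0226), Ier5l (-0.55, 0.0482), Wfikkn1 (-0.52, 0.0413) and the pentose phosphate enzyme gene Rpia (-0.51, 0.0243).

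Subunit genes of receptors for GABA and glutamate were among those that rose in PTZ+Q808 versus control. Gabrb2, the GABA-A receptor beta 2 subunit gene, rose from 15.0 ± 2.41 FPKM (SD, n = 4) to 23.2 ± 2.09 (n = 5), with 20.3 ± 0.995 in PTZ (log2 change 0.60 ± 0.0882, SE, adjusted p = 0.00893). The list of GABA synthesis, transport and receptor genes was not called (adjusted p = 0.0778). It held 2 genes past the threshold over all genes, Gabrb2 among them, and 7 of 23 adjusted over the list alone, 5 higher and 2 lower. Among the 7, values were higher for Gabrb2, Gabra2 (0.40) and Gabrg1 (0.33) and lower for Gabrd (-0.49) and Slc32a1 (-0.33). Gabrd and Slc32a1 were named after their values were seen. The AMPA receptor subunit genes Gria2 (0.38, 61.2 to 80.1 FPKM, adjusted p = 0.0352), Gria3 (0.34, 0.0241) and Gria4 (0.37, 0.0348) rose and were the 3 past the threshold adjusted over the glutamate receptor and transporter list alone. That list was not called (adjusted p = 0.286), and Grik1 (0.22, 0.194) did not pass. The synaptic adhesion gene Nlgn1 (0.47, adjusted p = 0.0199) and the calcium channel subunit gene Cacna2d1 (0.47, adjusted p = 0.0215) rose, each as the 1 member of its list past both thresholds. Snap25 (0.27, 0.0813), Dlgap1 (0.13, 0.276), Cacnb4 (0.36, 0.076), Scn2a (0.30, 0.107) and Cacna1e (0.24, 0.111) did not pass. Elavl2, an RNA binding protein gene and CA3 marker, rose (0.33, adjusted p = 0.0465), and Bok (-0.31, 0.152), Prkcd (-0.78, 0.273) and Nectin3 (0.24, 0.275) of the same list did not pass. The Prkcd value rested on control replicate 2 (43.1 FPKM, 6.53 to 13.7 in the other controls) and was -0.26 without it, and Nectin3 was 0.09 without the 3 libraries low in Ttr. The lists of synaptic, channel and CA3 and CA2 genes were not called (adjusted p = 0.141, 0.649 and 0.788).

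**Figure D2:**
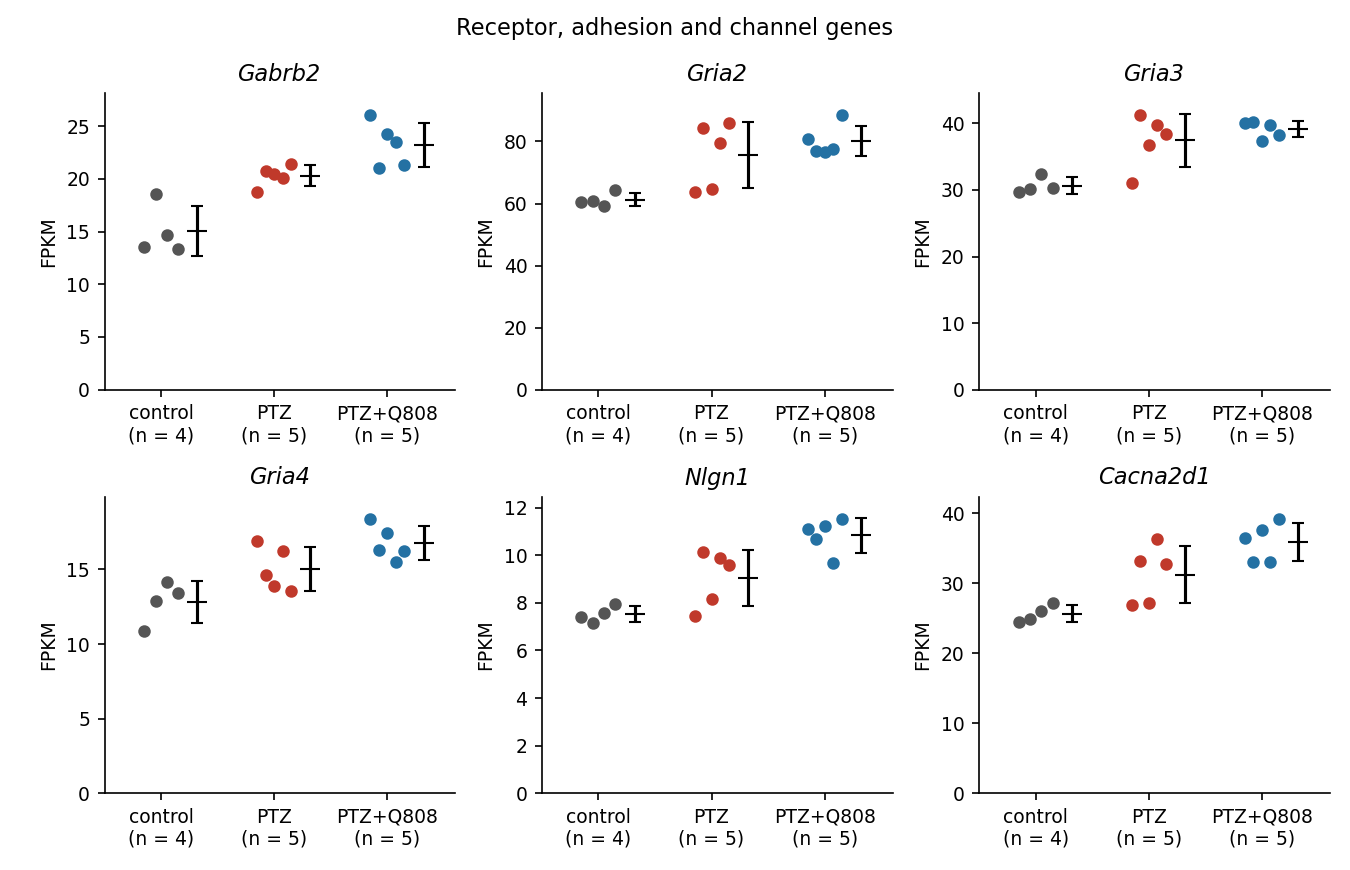
FPKM of Gabrb2, Gria2, Gria3, Gria4, Nlgn1 and Cacna2d1 in each library of control (n = 4), PTZ (n = 5) and PTZ+Q808 (n = 5), with 1 point per library and, beside the points, the mean with SD as error bars. For each gene the PTZ mean lay between the other means, as for Gabrb2 at 15.0, 20.3 and 23.2 FPKM. The genes were selected for a difference between PTZ+Q808 and control. Such selection mostly gave this order in simulated data without group differences, so it cannot be read as a graded change.

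Camera at the preset correlation called 6 lists in PTZ+Q808 versus control, each with an adjusted p of 0.998 with an estimated correlation and of at least 0.855 in the exact permutation. The immediate early, circadian and glucocorticoid lists shared Per1, which passed over each of these lists alone. Immediate early genes were higher in 34 of 34 members (median log2 change 1.22, adjusted p = 8.57e-20, exact permutation p = 0.0317), with 8 past the threshold over all genes and 28 adjusted over the list alone. Circadian clock genes were higher in 13 of 17 members (median 0.16, adjusted p = 0.0221, exact permutation p = 0.0397). Ciart (0.78, adjusted p = 0.0451), Bhlhe40 (0.63, 0.0477) and Nr1d2 (0.28, 0.0387) rose. Over the list alone 5 higher and 1 lower gene passed, the lower 1 being Cry1 (-0.34), named after its value was seen. Glucocorticoid-induced genes were higher in 13 of 20 members (median 0.23, adjusted p = 0.0223, exact permutation p = 0.0159). Nfkbia and Errfi1 (0.83, adjusted p = 0.0331) passed over all genes and 6 adjusted over the list alone, Klf9 (0.48) and Sgk1 (1.04) among them. Cholesterol synthesis genes were lower (5 of 19 members with positive values, median -0.14, adjusted p = 0.0307, exact permutation p = 0.0794). Fdft1 (-0.28, adjusted p = 0.024) and Dhcr7 (-0.28, 0.0374) fell. Adjusted over the list alone 6 lower genes passed, Mvd (-0.28) and Fdps (-0.23) among them, and 1 higher gene, Idi1 (0.50, named after its value was seen). Meningeal and fibroblast markers were higher in 15 of 15 members (median 0.57, adjusted p = 0.0221, exact permutation p = 0.159), among them Dcn (0.72), Col1a2 (1.45), Mgp (0.50) and Col3a1 (0.80). Their list mean was above the controls in PTZ+Q808 replicates 1 (3.69), 2 (3.50) and 3 (3.96) and within the range of the controls in PTZ+Q808 replicates 4 (2.39) and 5 (2.41). Myelinating oligodendrocyte markers were lower (2 of 16 members with positive values, median -0.37, adjusted p = 0.0221, exact permutation p = 0.262), among them Mag (-0.49), Hapln2 (-0.43), Cnp (-0.43) and Mbp (-0.47). The meningeal and the myelinating list had 0 members past either threshold. Lists not called held Sox9 with Gpr37l1 (-0.20), Aldh1l1 (-0.32) and Aqp4 (0.31) as astrocyte markers (adjusted p = 0.162). Nfkbia stood with Ifit3 (1.01), Vcam1 (0.23) and Cebpb (0.47) among NF-kB genes, also not called as a list (adjusted p = 0.12). Calls other than that of immediate early genes ended without control replicate 1 or 2 (circadian, glucocorticoid, cholesterol and myelinating), PTZ replicate 4 or PTZ+Q808 replicate 5 (cholesterol) or PTZ+Q808 replicate 3 (meningeal and myelinating), with highest adjusted p over all alternatives of 0.109 to 0.28. They also ended with a replicate block (glucocorticoid), when only the 2 groups compared were fitted (cholesterol) and without the 3 libraries low in Ttr (meningeal).

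**Figure D3:**
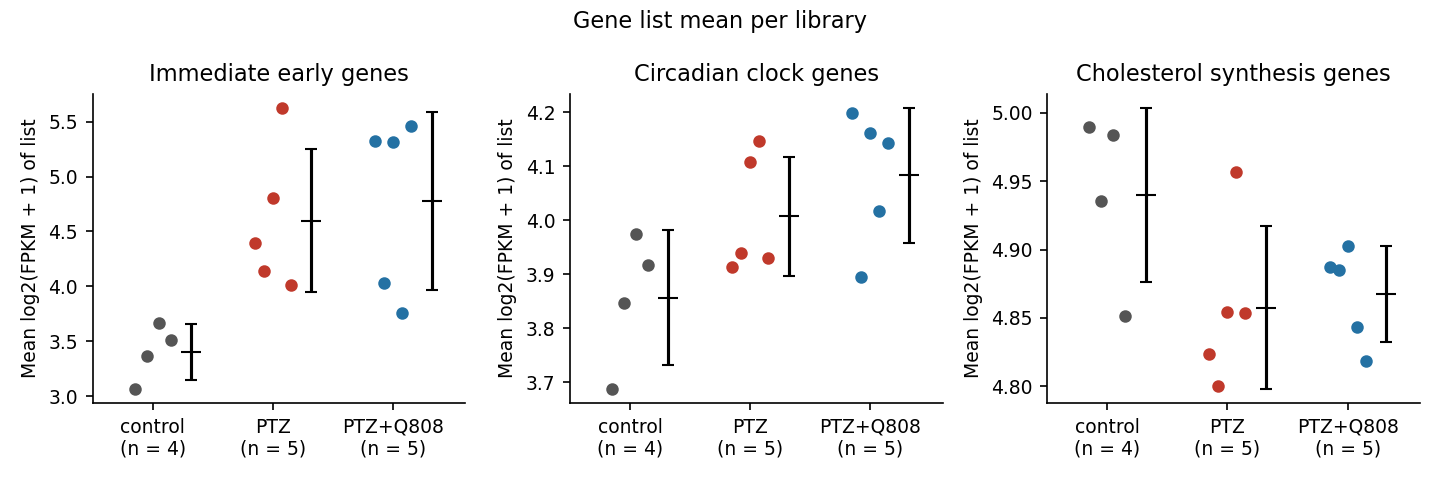
Mean log2(FPKM + 1) of the immediate early, circadian clock and cholesterol synthesis lists in each library of control (n = 4), PTZ (n = 5) and PTZ+Q808 (n = 5), with 1 point per library and, beside the points, the group mean with SD as error bars. Means of the immediate early list were 3.40, 4.60 and 4.78.

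Of the 366 genes called in PTZ+Q808 versus control, 365 had the same direction in PTZ versus control and 362 in PTZ+Q808 versus PTZ. In simulated data without group differences as many genes of smallest p gave 93% (88% to 96.2%) and 88.2% (83.1% to 91.5%), against 99.7% and 98.9% here. The 366 genes had smaller p than those of the simulated sets. Stronger selection raises both shares, so the excess cannot be read as an effect. The 4 genes called in PTZ versus control, Cyr61, Apold1, Zfp36 and Nfkbia, were among the 366 (0.0775 by chance for independent lists, though both comparisons share the controls). The median gene had 54% of its change already in PTZ, against 55.7% (49.3% to 61.6%) in the simulated data. Across all genes the changes from control in PTZ and in PTZ+Q808 had r = 0.788, where the shared controls alone gave 0.555, and r had a median of 0.322 (0.208 to 0.451 over 6 splits) when no control library was shared. The plot of changes against control shows the called genes.

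**Figure D4:**
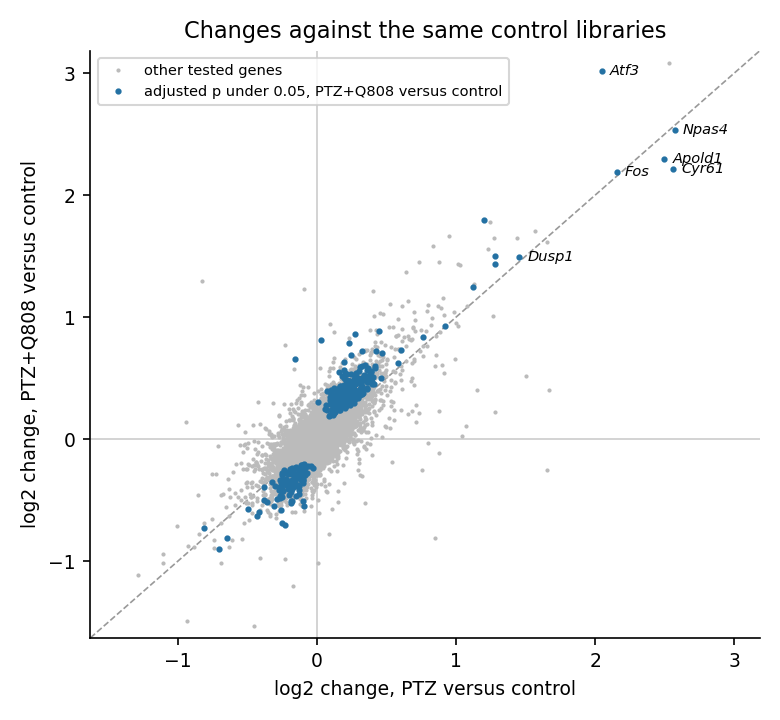
Log2 change of each of 12744 tested genes in PTZ versus control (horizontal axis) and in PTZ+Q808 versus control (vertical axis), with 1 point per gene, the 366 genes called in PTZ+Q808 versus control in blue and a dashed line of equal change. Both axes share the 4 control libraries, which alone gave r = 0.555 in simulated data.

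Unadjusted p was under 0.05 for 2638 genes in PTZ+Q808 versus control (637 by chance), and the groups did not overlap for 1136 genes, 8.91% against 1.59% by chance, including 337 of the 366. The count of 366 was 17 without control replicate 1, 40 without control replicate 3, and 54 without control replicate 4. It was 32, 72 and 38 without PTZ+Q808 replicate 1, 3 and 5, in this order, and 673 without PTZ+Q808 replicate 4. The count was 0 in limma without the 3 libraries low in Ttr (a fit added after the data had been seen), 199 when only the 2 groups compared were fitted, 190 with no filter, 4 with a replicate block, 564 with a term for Y-linked transcripts and 1100 with weights per library. Among libraries with Y-linked transcripts (3 PTZ+Q808, 2 control) 0 genes passed in limma (1546 with an unadjusted p under 0.05). Among those without (2 and 2) 5 passed, Apold1, Fos, Nhp2, Npas4 and Zfp36. The effect on the mean of immediate early genes was 1.16 with and 1.80 without Y-linked transcripts (difference 0.64, exact permutation p = 0.667).

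The other lists were not called in any comparison by camera at the preset correlation, and the adjusted p given is the smallest over the 3 comparisons. It was 0.0606 for astrocyte homeostatic markers, 0.817 for reactive astrocyte genes, 0.173 for microglia markers, 0.389 for oligodendrocyte precursor markers, 0.224 for endothelial and mural markers, 0.286 for ependymal markers, 0.655 for choroid plexus markers and 0.173 for red blood cell markers. Among neuronal groups it was 0.898 for dentate granule cell markers, 0.314 for CA3 and CA2 markers, 0.622 for interneuron markers, 0.173 for thalamus markers, 0.173 for neuropeptides, 0.0658 for GABA genes, 0.0641 for glutamate receptor and transporter genes, 0.12 for late activity-regulated genes and 0.12 for adult neurogenesis and proliferation genes. It was 0.898 for cytokines and chemokines, 0.649 for heat shock and unfolded protein response genes, 0.63 for apoptosis and DNA damage genes, 0.12 for nuclear oxidative phosphorylation genes, 0.107 for cytosolic ribosomal protein genes and 0.655 for xenobiotic response genes. The median, mean and test of a list differed in sign in at least 1 comparison for cytokines, dentate granule, heat shock, interneuron, neocortex, neuropeptide, oxidative phosphorylation, oligodendrocyte precursor, reactive astrocyte, thalamus, xenobiotic and cholesterol lists, in each case in a comparison where the list was not called.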

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

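The tests of the Y-linked share, choroid plexus, Y-linked status of the immediate early genes, scaling and blood were chosen after the results were seen, while the counts over other splits and the test of neutrophil precursor genes were chosen before the values they measure were seen. In each group of 4 or 5 libraries, the gap between the highest or lowest library and the nearest other was compared with the range of the group. Chance sets a library apart in about 1 in 20 groups, which gives 21 of 426 groups, and 33 were seen. The groups are not independent, since 8 flagged genes were of PTZ replicate 4 and 4 of control replicate 2. Genes were compared as FPKM rather than as log2 values, so the chance rate is approximate. The excess over 21 was not tested.

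PTZ replicate 4 stood above the other PTZ libraries for 8 genes, Atf3 (28.7 FPKM, next 4.99), Nr4a2 (59.1), Maff (6.53), Per1 (26.7), Nfil3 (9.96), Ifit3 (6.16), Homer1 (25.4) and Rsrp1 (84.4). Control replicate 2 stood above the other controls for the striatal genes Drd2 (29.4 FPKM, next 2.01), Gpr6 (12.9), Ppp1r1b (241) and Syndig1l (56.6) and for the mean log2 value of striatum markers (5.42, next 2.81). PTZ+Q808 replicate 3 stood apart for Prl (395 FPKM, next 0.71), Gh1 (206, next 0.56), Wfikkn1 (0.372, lowest), Dlgap1 (25.6, lowest) and the list mean of adult neurogenesis and proliferation genes (3.49). PTZ+Q808 replicate 2 stood apart for Sv2b (80.1 FPKM, lowest), Mtif2 (6.93), Fdps (101) and the list mean of nuclear oxidative phosphorylation genes (7.37), and PTZ+Q808 replicate 4 for the list mean of oligodendrocyte precursor markers (3.96). Among controls, replicate 3 was highest for Dcn (18.3 FPKM), replicate 4 for Cacna1e (28.9), Prl (0.444) and the glutamate receptor and transporter list (4.41), and replicate 1 was lowest for Cacnb4 (5.79). In the PTZ group, replicate 1 was highest for Col1a2 (9.35 FPKM) and Gh1 (8.52), replicate 2 for C1qtnf9 (1.39) and replicate 5 for Mbp (2490), and replicate 3 was lowest for Bok (25.1).

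In PTZ versus control, a count of 4 genes was reached by 1 of 100 splits of the libraries, the real 1 (highest other 1 gene). Chance is argued against as the source of that count, though not excluded. In PTZ+Q808 versus PTZ chance cannot be excluded, since any split reaches a real count of 0 (0 genes in limma, 783 with an unadjusted p under 0.05), as all 100 splits did, so that this count cannot decide. The highest other split gave 193 genes, more than the treatment did, with PTZ replicates 1 and 2 and PTZ+Q808 replicates 1, 2 and 3 on 1 side. These were the 5 of the 10 libraries with the highest means of 4 lists, meningeal and fibroblast markers (3.31 to 4.19, against 2.30 to 2.58 in the others), red blood cell markers (5.34 to 5.98, against 3.98 to 4.90), reactive astrocyte genes (2.95 to 3.36, against 2.72 to 2.90) and CA3 and CA2 markers (4.07 to 4.21, against 3.84 to 4.06). Whether meninges, blood or another difference set them apart was not tested.

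The first pattern weighed is the 366 genes called in PTZ+Q808 versus control. Of 100 splits 2 reached that count, the real 1 and another with 406 genes that moved PTZ+Q808 replicate 4 alone to the control side. Chance is argued against but not excluded. A split that mixed PTZ and PTZ+Q808 libraries called 193 genes, so differences between libraries other than treatment can give many calls. A different share of libraries with Y-linked transcripts is argued against by the shares themselves, 2 of 4 control and 3 of 5 PTZ+Q808 libraries. With a term for Y-linked transcripts 366 of the 366 genes passed in the same direction. Shares this close leave such a term little to remove, so that count adds no support. Choroid plexus markers differed little between the group means (3.51 ± 1.51 in control, SD, n = 4, and 3.65 ± 1.25 in PTZ+Q808, n = 5). A covariate for choroid plexus could thus remove little of a group difference. With log2 Ttr as that covariate 292 of the 366 passed in the same direction (79.8%). The median absolute log2 change was 0.38 before and 0.381 after. Without the 3 libraries low in Ttr the count was 0 in limma. The same genes then had a median absolute log2 change of 0.365. With 11 libraries in place of 14 their median SE was 0.0963 in place of 0.0816. These fits do not decide whether choroid plexus was part of the cause. An effect of PTZ, of Q808 or of both stays open as a hypothesis, and the design has no group that received Q808 without PTZ.

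The spread of the immediate early genes among the 10 PTZ-treated libraries is the next pattern, with list means from 3.76 to 5.63. A difference in scaling is argued against, since the median log2 value of all tested genes spanned 0.0991 over these libraries against 1.87 for the list mean. That median cannot test depth, because FPKM are already scaled by library total. Relative depth, estimated from the steps of low values, ran from 0.886 to 1.07 over the 14 libraries. That estimate searched only near equal depth and could not return a large difference, so depth was not tested. Libraries without Y-linked transcripts had list means 1.03 higher than those with them (exact permutation p = 0.04, 100 arrangements within groups), so that sex may be a candidate source of the spread, found and tested on the same data. The treatment effect itself was not shown to differ with Y-linked status (exact permutation p = 0.533 in PTZ versus control, n = 4 and 5). Time from seizure to sampling and the strength of each seizure stay open and untested, as neither was given in the sources used here.

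The last pattern is the neutrophil granule genes Mpo, Elane and Prtn3 in PTZ+Q808. Blood high enough to set all 5 PTZ+Q808 libraries apart is argued against, since Hbb exceeded the highest other library in 1 of 5. A smaller rise in blood stays open. By camera at the preset correlation, red blood cell markers were higher in 7 of 7 members against PTZ (median log2 change 0.33, adjusted p = 0.173). Against control they were higher in 6 of 7 (0.16, adjusted p = 0.649). Transcripts of neutrophil precursors may be a candidate source. Of 6 other primary granule and precursor genes listed, 4 were above 0 in at least 5 libraries and were tested. Of these, 0 lay higher in all 5 PTZ+Q808 libraries than in every other library, which met the bound set beforehand against this explanation. The highest of these genes reached 0.598 FPKM, so values near the floor decide nothing and the bound was wrongly set. The pattern itself has the same limit, with Elane at 0.144 to 0.263 FPKM in PTZ+Q808. No biological explanation for an effect of Q808 on these genes was tested.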

How the results depend on the processing

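The fits with a Y-linked term, with log2 Ttr and without the 3 libraries low in Ttr were chosen after the results were seen. Of 3544 values of named genes under alternatives, 3135 kept direction and side of the threshold, 357 kept direction but no longer passed, 52 newly passed and 0 reversed. Many named genes did not pass in the reported fit, and these count as kept where they again did not pass. All 357 losses thus fell on called genes. In PTZ+Q808 versus control, Apold1 passed in 26 of 27 alternatives, Atf3 in 10, and Gadd45g, Ier5l and Bhlhe40 in 9 each. In PTZ versus control, Apold1 passed in 25 of 27 and Zfp36 in 12. Of 570 values of gene lists, 439 kept both, 130 kept direction alone and 1 reversed, the striatum list in PTZ versus control without control replicate 2 (median log2 change 0.0748, adjusted p = 0.433, range over alternatives 4.39e-06 to 0.433), which control replicate 2 had carried. The count of 4 genes in PTZ versus control was 1 with no filter, where more genes were tested, 0 when only the 2 groups compared were fitted, 7 with weights per library, 0 with a replicate block, 8 with a Y-linked term and 2 with log2 Ttr. It was 25 at an unadjusted p under 0.05 and at least 2-fold, and 1 to 5 when each library was left out in turn. The count of 0 in PTZ+Q808 versus PTZ (limma, 783 unadjusted) was 2 with no filter (Mpo and Elane), 3 at an unadjusted p under 0.05 and at least 2-fold (Avp, Nhp2 and LOC103690108, named after their values were seen), 0 with a replicate block and 0 to 0 when each library was left out. The count of 366 in PTZ+Q808 versus control was 190 with no filter, 199 when only the 2 groups were fitted, 1100 with weights per library, 4 with a replicate block, 564 with a Y-linked term and 0 without the 3 libraries low in Ttr. It was 35 at an adjusted p under 0.05 and at least 1.5-fold, 40 at an unadjusted p under 0.05 and at least 2-fold, and 17 to 673 when each library was left out. Genes changed by PTZ with the opposite change under Q808 numbered 0, as they had to with 0 genes called in PTZ+Q808 versus PTZ, and were 1 (LOC103690108) at an unadjusted p under 0.05 and at least 2-fold and 0 to 0 when each library was left out, again fixed by the count of 0. The correlation across genes of the PTZ and Q808 effects was -0.0917 with a pseudocount of 0.1, -0.119 with no filter, and 0.0829 at a minimum FPKM of 5. It was 0.0674 with weights per library, -0.163 without the 3 libraries low in Ttr, -0.0239 with a replicate block, and -0.147 to 0.0782 when each library was left out. Except where fewer samples, more genes or another threshold account for a change by construction, the cause was not tested. Replicate numbers were not seen to pair the libraries, since 0 of 14 best matched the library of the same number in another group (correlations of same-numbered pairs -0.28 to 0.143). Differences between whole libraries can hide a weaker shared factor such as a day, litter or batch, which was not excluded. The count-based test was not run, as the files used hold FPKM alone, and depth limits genes of low FPKM most, by an amount that the files do not give.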

Other observations

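The enrichment and the genes tested without a filter were chosen after the results were seen. Genes annotated to mRNA binding were frequent among those that rose in PTZ+Q808 versus control, with 15 of 136 tested members called higher where 2.71 were expected (adjusted p = 0.000248 over 3139 terms, 237 annotated called genes of 11915). They included Celf4, a regulator of neuronal mRNA (79.9 ± 3.80 FPKM in control, SD, n = 4, and 103 ± 6.33 in PTZ+Q808, n = 5, log2 change 0.36 ± 0.0683, SE, adjusted p = 0.0226), and Elavl4, which encodes the neuronal RNA binding protein HuD (12.1 ± 1.49 to 16.9 ± 1.06 FPKM, 0.45, adjusted p = 0.0226). Others were the nonsense-mediated decay factor gene Upf3b (0.42, adjusted p = 0.0322), the AU-rich element binding protein gene Hnrnpd (0.34, adjusted p = 0.0329), the translation initiation factor genes Eif2a and Eif3a, the splicing-related genes Luc7l3, Nsrp1, Hnrnpa1 and Hnrnpa3, and Myef2, Fyttd1, Rbm25l1, Tpr and Zfp36. The next term, histone binding, did not pass (9 of 93 members, 1.85 expected, adjusted p = 0.148). Hnrnpa1 has related gene copies, and reads shared between copies were not tested. The enrichment treats genes as independent, and the 366 called genes behind it depend on single libraries (17 without control replicate 1, 673 without PTZ+Q808 replicate 4).

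Without a filter, 2 genes passed in PTZ+Q808 versus PTZ, both neutrophil granule genes. Mpo, which encodes myeloperoxidase, was 0.552 to 1.62 FPKM in the 5 PTZ+Q808 libraries and at most 0.0756 in the other 9 (log2 change 1.00 against PTZ, adjusted p = 0.00222, and 0.97 against control, adjusted p = 0.00427). Elane, which encodes neutrophil elastase, was 0.144 to 0.263 against at most 0.0621 FPKM (0.24, adjusted p = 0.00222, and 0.26, adjusted p = 0.00389). Prtn3 was 1.23 to 2.72 FPKM, with 4 of 5 libraries above the highest other (1.24), and did not pass without a filter (adjusted p = 0.839 against PTZ). Later granule and mature neutrophil genes were higher in all PTZ+Q808 libraries than in every other library for 0 of 8 members, with Mmp8 above the highest other in 3 of 5 libraries and S100a9 in 1. Over 18961 genes, 36 were higher and 20 lower in all PTZ+Q808 libraries than in every other library, where chance gives 18.9 for both directions together.

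PTZ+Q808 replicate 3 also held the pituitary transcripts Pomc (74.7 FPKM, next highest library 3.15) and Cga (8.70, next 1.72). Of 11 other pituitary markers with a median under 1 FPKM elsewhere, 5 were highest in this library by at least 2-fold, Cga, Tshb, Pou1f1 and Six6 among them, which missed the bound of 6 set beforehand for pituitary tissue, and Fshb was listed at 0 in every library. Of 7 markers with a median of at least 1 FPKM elsewhere, 2 were highest in this library. No other PTZ+Q808 library (0 of 4) held Prl more than 1 FPKM above the highest control. Npy, a neuropeptide gene of hippocampal interneurons, reached at most 0.207 FPKM in any library, and 3640 genes were listed at 0 in every library. Whether the gene model or the assignment of reads lowered the Npy values was not tested.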
